A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

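Grains of the rice line Zhenong 34 (wild type, 3 libraries) and of the sgs3 mutant (3 libraries) were sequenced. Per the labels, total RNA was made into libraries with a SMARTer mRNA kit and run on an Illumina HiSeq instrument. Small RNA libraries, which the series title names, are not analysed here. The submitters' processing notes list HISAT2 2.1.0, Bowtie2, RSEM, StringTie and DESeq2 1.12.4 without saying what each was used for. The genome build and annotation are not given in the sources used here, and gene IDs are MSU locus names.

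The deposited gene table held TPM values computed by the authors, with 2 decimals and library sums between 967526 and 994306, although it is named as counts. The authors recorded no scaling between libraries. The read depth behind these values is unknown, so counting error could not be set beside the spread between libraries. The authors' deposited splicing tables held inclusion levels as a fraction from 0 to 1, per library and as a mean per group, computed from junction reads divided by the effective length of each form. Per the file headers they also held junction reads per library, with a p-value and an FDR from the authors' own test on junction reads, whose program is not given in the sources used here. In the deposited splicing tables the group headings of the read columns contradicted those of the inclusion columns. Reads headed wild type gave the inclusion levels headed sgs3 to within 0.0005 in every event. Groups were taken from the inclusion headings, since in genes changed at least 2-fold in TPM the reads headed wild type followed the TPM of the mutant in 97.2% of 4196 events. Libraries within a cell carried no replicate number. Exon skipping had 3 libraries per group, and the other kinds had 3 mutant and 2 wild-type libraries. Coordinates were counted from 1.

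A count-based test had been planned for the gene table and could not be used, because the table holds TPM. The alternative named beforehand was used instead: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(TPM + 1), for genes with a TPM of at least 1 in at least 3 libraries, and Benjamini-Hochberg adjusted p under 0.05. It leaves 4 residual degrees of freedom. TPM is relative to each library's total, so all gene results were also computed after median-of-ratios scaling between libraries. Gene lists were tested against other genes with limma's camera at a preset correlation of 0.01, for lists with at least 5 tested members, and again with an estimated correlation and with fry. Annotation terms with 10 to 500 tested genes were tested with a one-sided Fisher's exact test for risen and fallen genes separately, against all tested genes.

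Splicing events with at least 20 junction reads in every library were tested with a quasi-binomial logistic model whose dispersion was moderated by limma (7.53 prior degrees of freedom). An event was called at an adjusted p under 0.05 over all kinds with a difference of at least 0.1. The tested events had a median of 595 reads over their libraries together. The overlap of gene and splicing calls was tested with a two-sided Fisher's exact test. Shares of TPM were compared with exact permutation tests over all assignments of the 6 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

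The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the SGS3-annotated genes and 4 auxin response factors, the 8 largest rises and 8 largest falls, and the 3 members with the smallest p of each called list and of 4 chosen lists. The rises and falls were taken among called genes with non-overlapping groups, a mean of at least 5 TPM in the higher group and an informative description. For each kind of splicing event the 2 called events with the smallest p were named. Genes named outside this rule are said to be so where they appear.

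On simulated changes put into the tested genes, limma found 0 of 67 genes changed by 1 on the log2 scale, 27 of 67 changed by 2 and 53 of 66 changed by 4, with 5 calls outside the changed set. The splicing model found 6 of 67 simulated differences of 0.1, 15 of 67 of 0.2 and 42 of 66 of 0.3, with 15 calls outside the changed set. In these simulations small changes were therefore mostly missed. The 15 splicing calls outside the changed set were as many as those found at 0.2, so false calls also occurred. A simulated splicing call needed only an adjusted p under 0.05, without the minimum difference of 0.1, and the spread was set at a fixed value. These splicing counts therefore do not measure the recovery or the false calls of the full rule. In the data some genes changed by about 1 on the log2 scale were called on TPM, such as APO protein 1 (LOC_Os04g52520, -1.01). The simulated recovery may therefore not carry over to these libraries.

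Alternatives covered scaling, filters, pseudocounts, thresholds, each library left out in turn, the replicate number as a block, other list and term tests, read minimums and the authors' splicing calls. Replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.53, 0.21 and -0.09 across genes. Lists were matched to the table by description patterns and locus names, with RAP identifiers assigned to MSU loci by hand from known pairs and the table's descriptions, so some hold unrelated members. In the gene table, 3 lines were empty and are not used here, and 31020 genes have no description.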

Results

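Rice grains of the wild-type line Zhenong 34 were compared with grains of an sgs3 mutant whose treatment label reads EMS. EMS (ethyl methanesulfonate) is a chemical that makes mainly point mutations. The stage of the grains is not in the labels. Each group had 3 libraries of messenger RNA, and the single contrast of the design was mutant against wild type. Gene expression was given as TPM, whose sum per library lay between 967526 and 994306. TPM keeps no sequencing depth, so the depth behind the gene values is unknown. Of 55983 genes listed, 16352 reached 1 TPM in at least 3 libraries and were tested. Junction reads were given for 5 kinds of splicing event. For exon skipping they summed to between 1955339 and 2581535 per library. The labels did not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical.

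Transcripts of seed storage proteins, the glutelins, prolamins and globulins that fill the rice endosperm, took a larger share of every mutant library than of any wild-type library. Their share of TPM was 52.4% ± 3.69 (SD, n = 3) in the mutant and 27.2% ± 17.3 (SD, n = 3) in the wild type. Cytosolic ribosomal protein transcripts moved the other way, with 1.27% ± 1.10 (SD, n = 3) of TPM in the mutant and 8.92% ± 6.68 (SD, n = 3) in the wild type. For each of these shares the 2 groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. Wild-type replicate 1 stood apart, with storage transcripts at 8.0% of TPM against 41.5% and 32.2% in wild-type replicates 2 and 3. Its ribosomal protein share was 16.4%, against 3.68% and 6.62%. Its log2 values correlated at 0.87 with each of the other wild-type libraries across genes, which are not independent replicates, while those 2 correlated at 0.95. Mutant libraries correlated with each other at 0.93 to 0.97, and libraries of different groups at 0.67 to 0.93. Mutant replicate 3 correlated at 0.93 and 0.92 with wild-type replicates 2 and 3. Those libraries were thus closer to it than to wild-type replicate 1.

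**Figure D1:**
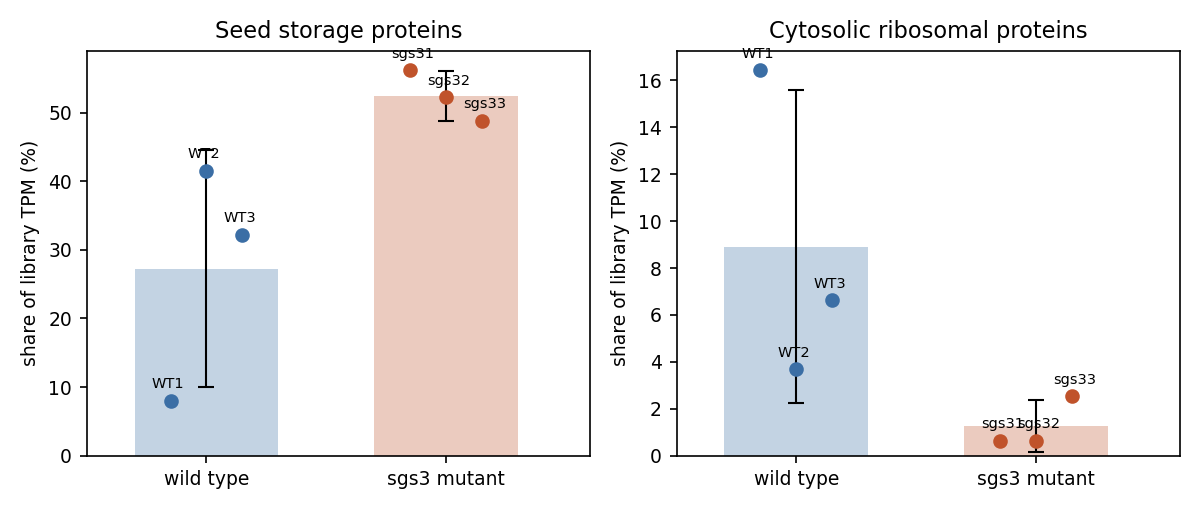
Share of each library's TPM (%) taken by the seed storage list (left) and the cytosolic ribosomal list (right), by group. Points are libraries, bars are group means and error bars are 1 SD (n = 3); storage shares are 48.8% to 56.2% in the mutant and 8.0% to 41.5% in the wild type.

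The gene annotated as a homolog of SUPPRESSOR OF GENE SILENCING 3 (LOC_Os12g09580, chromosome 12) was lower in the mutant. SGS3 is a plant protein that works with RNA-dependent RNA polymerase in making trans-acting small interfering RNAs. The labels do not say which gene is mutated or what sgs3 stands for. The gene had 94.92, 40.86 and 53.45 TPM in the wild type and 8.73, 11.59 and 29.24 TPM in the mutant. The log2 fold change was -1.96 (SE 0.51, limma adjusted p = 0.0436), and -0.90 (SE 0.29, adjusted p = 0.0979) after median-of-ratios scaling, where it no longer passed over all genes. Adjusted over the list alone, a list of the 2 SGS3-annotated genes, it fell on TPM and after scaling. On TPM it passed without wild-type replicate 2 or mutant replicate 3 and missed the threshold without any 1 of the other 4 libraries. The neighbouring copy, LOC_Os12g09590, had 3.50 ± 0.16 TPM in the wild type and 2.68 ± 0.69 in the mutant (SD, n = 3; limma adjusted p = 0.417). In Arabidopsis such small RNAs target auxin response factors. None of the 4 rice target genes passed the test on TPM. ARF3 (LOC_Os01g54990) had 18.6 ± 8.05 TPM in the wild type and 9.44 ± 1.67 in the mutant (SD, n = 3; limma adjusted p = 0.102). ARF2 (LOC_Os01g48060) had a log2 fold change of -0.13 (limma adjusted p = 0.762), ARF14 (LOC_Os05g43920) 0.0032 (adjusted p = 0.994) and ARF15 (LOC_Os05g48870) -0.37 (adjusted p = 0.429). After scaling these directions flipped for ARF3, ARF2 and ARF15 (0.19, 0.50 and 0.53) and for LOC_Os12g09590 (0.52), and ARF14 had 1.03. None of these passed over all genes after scaling, and adjusted over the list alone 2 of the 4 target genes, ARF14 and ARF15, rose.

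Between the genotypes, prolamin genes clustered on chromosome 5 were among those that rose most on the log2(TPM + 1) scale, and a set of other genes was seen in 1 genotype and nearly absent from the other. By limma on log2(TPM + 1), 253 genes rose and 4295 fell in the mutant at an adjusted p under 0.05. The median log2 fold change of the tested genes was -0.86. After median-of-ratios scaling, which set that median to 0.0028, 261 genes rose and 160 fell. The share of calls that fell was therefore 94.4% on TPM as deposited and 38.0% after scaling. Called in the same direction on both scales were 171 rises and 160 falls. The groups did not overlap for 56.3% of tested genes on TPM and for 37.9% after scaling. For a single gene chance gives 10%, but genes moved together, so the share under 1 split can lie far from that. Shares under the other splits were not computed. Fold changes on the log2(TPM + 1) scale understate the change of weakly expressed genes.

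Among the 8 largest rises, LOC_Os05g26368, a prolamin annotated PPROL 14E, went from 3.26 ± 2.60 to 551 ± 141 TPM (SD, n = 3), a log2 fold change of 7.26 (SE 0.58, limma adjusted p = 6.45e-04). Prolamins LOC_Os05g26720 and LOC_Os05g26690 rose by 6.35 (SE 0.42) and 4.23 (SE 0.66) on the log2 scale. Another prolamin, LOC_Os05g26250, was listed at 0, 0 and 0.1 TPM in the wild type and at 73.86, 47.7 and 51.07 TPM in the mutant. LOC_Os05g26410, annotated as a retrovirus-related polyprotein but with a locus number that lies among those of the prolamins, reached 10846 ± 1603 TPM in the mutant from 553 ± 449 (SD, n = 3). It passed limma's test on TPM (adjusted p = 0.0436) and not after scaling (adjusted p = 0.0624). Peroxisomal acyl-CoA oxidase 4 (LOC_Os06g23870), an enzyme of fatty acid oxidation, had 69.86, 76.88 and 83.66 TPM in the mutant and 0.09, 0 and 0 in the wild type. Glutathione S-transferase GSTU6 (LOC_Os10g38630) had 29.83, 44.64 and 52.06 TPM in the mutant and 0, 0.05 and 0 in the wild type. A putative disease resistance protein, RGA1 (LOC_Os01g05620), rose from 0.18 ± 0.09 to 35.8 ± 12.4 TPM (SD, n = 3; limma adjusted p = 3.82e-04). The prolamin copies share a description, and how alike their sequences are was not measured here. Reads may be split among them, so each copy's value is uncertain.

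Most of the largest falls were as clear-cut. Histone H2B.4 (LOC_Os01g05630) dropped from 120.0 ± 44.3 to 0.22 ± 0.13 TPM (SD, n = 3; log2 fold change -6.56, SE 0.38, limma adjusted p = 2.06e-04). The gene annotated Protein FAM63A (LOC_Os06g50630) dropped from 103 ± 17.8 to 1.08 ± 0.58 TPM (SD, n = 3). Transcription factor MYB3 (LOC_Os02g09670) had 23.19, 10.62 and 16.66 TPM in the wild type and 0, 0 and 0.07 in the mutant. An AC transposase (LOC_Os11g39940) and a Pol polyprotein of transposon 297 (LOC_Os05g15220) were listed at 0 in every mutant library and at 14.56 to 20.64 and 11.44 to 19.75 TPM in the wild type. The gene annotated Fork head transcription factor 1 (LOC_Os11g27530) fell by 4.04 on the log2 scale (SE 0.62, limma adjusted p = 0.0167). Ribosomal protein S11 (LOC_Os04g52361) and the prolamin LOC_Os05g26480 fell on TPM (log2 fold changes -5.44 and -5.21) but did not pass after scaling (limma adjusted p = 0.0715 for the former and adjusted p = 0.105 for the latter).

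The call count of the whole table rested on single libraries. Without mutant replicate 1, 2 or wild-type replicate 3 it dropped from 4548 to 99, 94 and 124 genes, and without wild-type replicate 1 to 405. Without wild-type replicate 2 it rose to 8124, without mutant replicate 3 it was 5820, and without filtering low genes it was 107. After scaling the counts were 296, 522 and 219 without wild-type replicates 1, 2 and 3, and 155, 151 and 2394 without mutant replicates 1, 2 and 3. On TPM with all libraries, 102 genes passed at an adjusted p under 0.01. Named genes with unadjusted limma p-values from 9.9e-04 to 0.0064 shared 1 adjusted p of 0.0436. Genes tied in this way pass or miss the threshold together.

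Of 35 gene lists fixed beforehand, 33 had at least 5 tested members, and limma's camera test with a preset correlation of 0.01 called 14 of them. It compares each list with the other genes, so a list can be called up while its median is below 0, because the median of all genes was -0.86. None of the 14 calls held with an estimated correlation, where every adjusted p was at least 0.838. With an estimated correlation no list had an unadjusted p under 0.05 either. By fry, limma's test of whether a list moves on balance in 1 direction, no list passed on TPM or after scaling, and 8 and 10 lists had an unadjusted p under 0.05. Set beside the tested genes as a whole, the lists are therefore given as counts and medians.

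Seed storage proteins had the highest median of all lists tested. Of 53 tested members, 11 rose, 5 fell and 37 did not pass, and the counts adjusted over the list alone were also 11 and 5. After scaling 9 rose and none fell (10 rose and 1 fell adjusted over the list alone). The list's median log2 fold change was 1.53 on TPM and 2.64 after scaling (camera adjusted p = 2.07e-33; 0.838 with an estimated correlation). Without wild-type replicate 1 the median was 0.46. The 3 members with the smallest p were the prolamins LOC_Os05g26250, LOC_Os05g26720 and LOC_Os05g26368 above. On TPM the risen members were PPROL 14E prolamins with nearby locus numbers on chromosome 5, and the Dof protein PBF (LOC_Os10g35300). No glutelin or globulin rose past the threshold. The fallen members were prolamins LOC_Os03g55734, LOC_Os03g55740 and LOC_Os05g26480, a globulin (LOC_Os05g02520) and the DNA-binding protein SMUBP-2 (LOC_Os03g38990). The list's pattern also took in a few genes that are not storage proteins.

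Cytosolic ribosomal proteins lay at the other end. Of 188 tested members 183 fell and none rose on TPM, with a median log2 fold change of -2.87 (camera adjusted p = 7.13e-15; 0.838 with an estimated correlation). After scaling the median was -1.78, and over all genes no member fell past the threshold and 1 rose. Adjusted over the list alone, 186 fell and 1 rose on TPM, and 178 fell and 1 rose after scaling. Ribosomal protein S29 (LOC_Os11g41610) had 476 ± 310 TPM in the wild type and 44.4 ± 42.0 in the mutant (SD, n = 3; limma adjusted p = 0.0434 on TPM and 0.0580 after scaling). Ribosomal protein L26-1 (LOC_Os01g04730) fell by 3.16 on the log2 scale (SE 0.65, limma adjusted p = 0.0436), and it missed the threshold after scaling (adjusted p = 0.0579). Wild-type replicate 1, with the highest ribosomal share, moved with this group, and without it the list's median was -2.29.

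Of 60 tested genes matched by the pattern of the histone list 21 fell, 1 rose and 38 did not pass (median -1.43; 34 fell and 1 rose adjusted over the list alone; adjusted p = 0.838 with an estimated correlation). After scaling 4 fell and 1 rose, with a median of -0.42 (5 fell and 1 rose adjusted over the list alone). Within the list neighbouring H2B copies moved apart, since H2B.4 fell as above while H2B.3 (LOC_Os01g05610) rose from 3.32 ± 2.17 to 59.0 ± 19.8 TPM (SD, n = 3; limma adjusted p = 0.0033). The locus number of the RGA1 gene above, which also rose, lies between those of these H2B genes. Whether reads were shared between the H2B copies was not tested. Histone H3.2 (LOC_Os12g22650) fell by 2.01 on the log2 scale (SE 0.32, limma adjusted p = 0.0176). These 3 histone calls held after scaling, with adjusted p-values of at most 0.0213. Splicing factors had 33 of 115 members that fell and 1 that rose, with a median of -1.08 that was -0.09 after scaling (adjusted p = 0.838 with an estimated correlation). Adjusted over the list alone 51 fell and 1 rose on TPM, and after scaling 1 rose and none fell. Small nuclear ribonucleoproteins G (LOC_Os03g29740) and F (LOC_Os02g08090) had log2 fold changes of -3.43 (SE 0.76) and -2.09 (SE 0.50) and passed on TPM only, and Sm D2 (LOC_Os01g73604) rose by 2.05 (SE 0.36, limma adjusted p = 0.0256).

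Genes of starch synthesis, the other main store of the grain, gave few calls. Of 23 tested members 1 fell and none rose, and none passed when adjusted over the list alone, where after scaling 1 rose. Their median log2 fold change of -0.31, which turned to 0.68 after scaling, was 0.55 above that of all genes (camera adjusted p = 0.0182; 0.838 with an estimated correlation). A gene annotated starch synthase 4 (LOC_Os02g56320) had 37.1 ± 5.22 TPM in the wild type and 15.4 ± 5.71 in the mutant (SD, n = 3; limma adjusted p = 0.0437 on TPM and 0.617 after scaling). Granule-bound starch synthase 1b (LOC_Os07g22930) had a log2 fold change of -1.33 (limma adjusted p = 0.0644), and a gene annotated as the small subunit of ADP-glucose pyrophosphorylase (LOC_Os09g12660) had -1.12 (adjusted p = 0.0741). Related genes named outside the rule did not pass. A second small subunit gene (LOC_Os08g25734) had 0.075 (limma adjusted p = 0.905) and a second starch synthase 4 gene (LOC_Os05g45720) had -0.50 (adjusted p = 0.283). Granule-bound starch synthase 1 (LOC_Os06g04200) had 0.48 (limma adjusted p = 0.452). In the list of sucrose cleavage and transport 3 of 29 members rose and 3 fell, with a median of -0.52 that turned to 0.37 after scaling (2 rose and none fell adjusted over the list alone, and 7 rose after scaling; adjusted p = 0.838 with an estimated correlation). The sugar exporter SWEET11 (LOC_Os08g42350), which feeds the developing endosperm, rose from 42.8 ± 7.39 to 187 ± 49.2 TPM (SD, n = 3; log2 fold change 2.08, SE 0.36, limma adjusted p = 0.0256), and it passed after scaling (adjusted p = 0.0226). Sucrose synthase 7 (LOC_Os04g17650) rose by 2.26 (SE 0.48, limma adjusted p = 0.0436) and invertase CINV1 (LOC_Os02g34560) fell by 1.28 (SE 0.36, adjusted p = 0.0436). Neither of these 2 passed after scaling.

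In the small RNA pathway 8 of 35 tested members fell, also when adjusted over the list alone, and none rose. The list's median of -0.84 was 0.0126 above that of all genes (camera adjusted p = 0.359; 0.838 with an estimated correlation). After scaling 1 fell and none rose, with a median of -0.04 (1 rose and 1 fell adjusted over the list alone). A gene annotated Dicer homolog 3a (LOC_Os08g05320), a small-RNA-producing endonuclease, had 2.98, 4.19 and 4.19 TPM in the wild type and was listed at 0 in all 3 mutant libraries (limma adjusted p = 0.0037, and 0.0180 after scaling). Another gene annotated Dicer homolog 3a, LOC_Os01g68120, picked out after its values were seen, did not pass (log2 fold change -0.87, limma adjusted p = 0.0804, and 0.894 after scaling). Argonaute 18 (LOC_Os07g28850) had 10.96, 8.89 and 10.16 TPM in the wild type and 2.47 ± 1.06 in the mutant, and a gene annotated argonaute 2 (LOC_Os03g52490) went from 180 ± 120 to 30.5 ± 26.4 TPM (SD, n = 3; limma adjusted p = 0.0436 for each). After scaling these had adjusted p-values of 0.0800 and 0.0897. The same description is carried by LOC_Os05g51180, which fell by 2.19 on the log2 scale, and by LOC_Os04g52540, which did not pass (log2 fold change -0.76, limma adjusted p = 0.129); both were picked out after their values were seen, and the former missed the threshold after scaling. Of 11 tested grain size genes 3 fell (6 adjusted over the list alone), with a median of -1.27 (camera adjusted p = 0.374; 0.838 with an estimated correlation). They were GW2 (LOC_Os02g14720), a ubiquitin ligase that limits grain width, and the alpha and beta subunits of the heterotrimeric G protein (LOC_Os05g26890 and LOC_Os03g46650). Their log2 fold changes were -1.34 (SE 0.32), -1.28 (SE 0.36) and -1.71 (SE 0.48), each with an adjusted p of 0.0436. After scaling they were -0.24, -0.26 and -0.66, and none passed, nor did any list member when adjusted over the list alone.

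**Figure D2:**
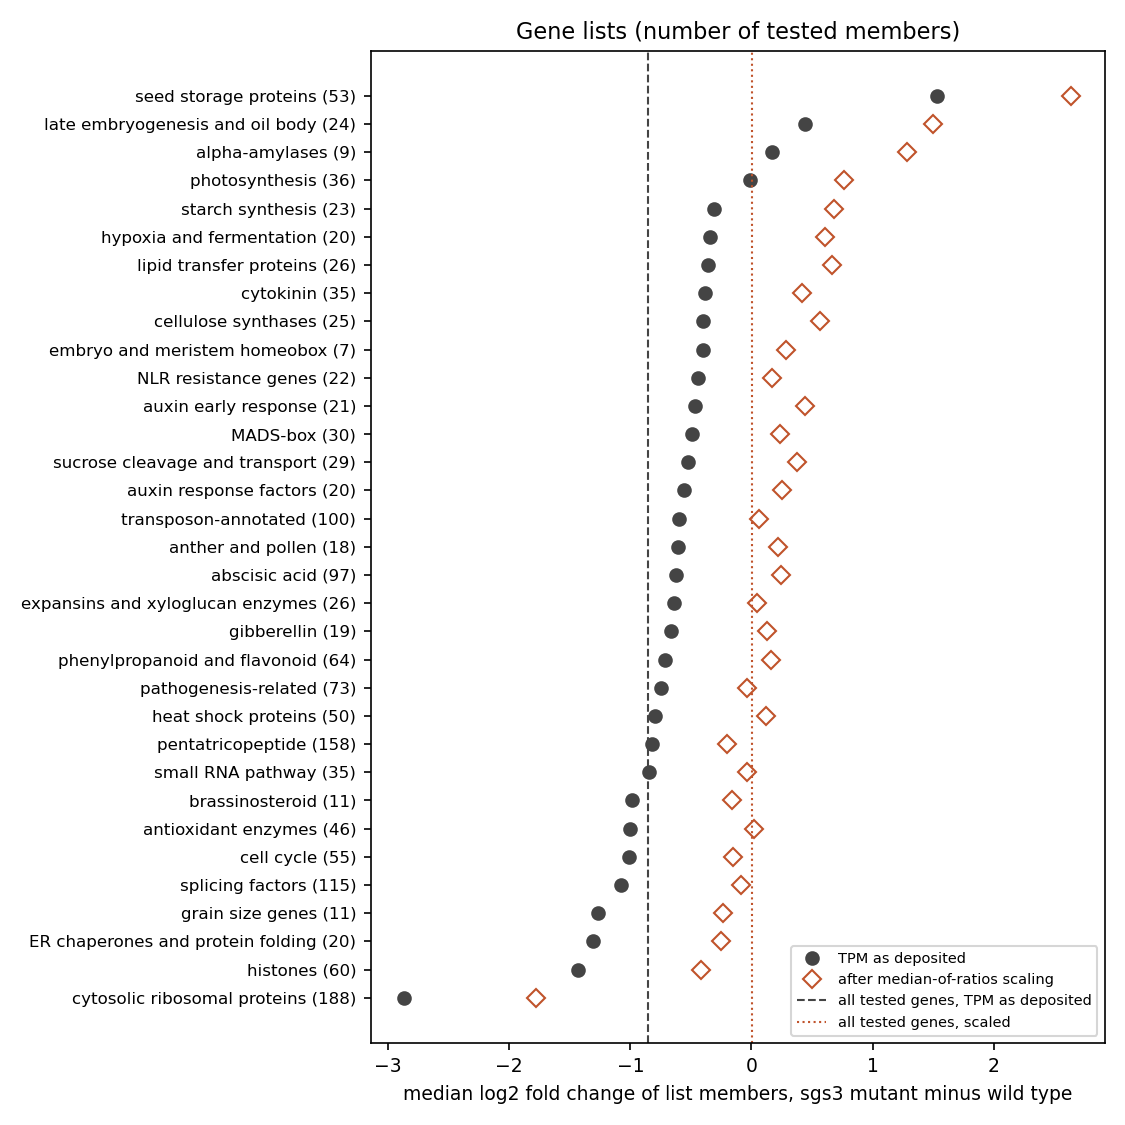
Median log2 fold change, mutant minus wild type, of the tested members of 33 gene lists, on TPM as deposited (filled circles) and after median-of-ratios scaling (open diamonds). Vertical lines mark the medians of all tested genes, -0.86 and 0.0028; seed storage proteins lie highest at 1.53 and cytosolic ribosomal proteins lowest at -2.87, and some medians change sign, as for starch synthesis (-0.31 to 0.68).

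Among the other lists called by the preset correlation, late embryogenesis and oil body genes, which mark the maturing embryo, had a median of 0.44 (1.499 after scaling) with none of 24 members past the test, also adjusted over the list alone, where after scaling 1 rose. Without wild-type replicate 1 the median on TPM was -0.08. Their first member by p, a Lea14-A protein (LOC_Os05g50710), had a log2 fold change of -0.73 (limma adjusted p = 0.0969) that turned to 0.36 after scaling, and dehydrin COR410 (LOC_Os02g44870) and a D-34 protein (LOC_Os06g23350) had -1.56 and 1.45. The alpha-amylase list had a median of 0.17 (1.29 after scaling) and no call among 9 members, also adjusted over the list alone, where after scaling 2 rose. It joined amylase 3B (LOC_Os09g28420, log2 fold change -1.08) to amylase inhibitors such as LOC_Os07g11630 and LOC_Os04g44470 (2.31 and 1.33). Photosynthesis genes had a median of -0.01 (0.77 after scaling), and 2 of 36 fell (none adjusted over the list alone, on TPM or after scaling), both low in these grains. They were a chloroplast peptidase (LOC_Os02g57060, 3.50 ± 2.22 to 0.56 ± 0.33 TPM) and APO protein 1 (LOC_Os04g52520, 4.32 ± 1.09 to 1.64 ± 0.47 TPM; SD, n = 3), neither called after scaling. PsbP domain protein 7 (LOC_Os01g70820) had a log2 fold change of -1.10 (limma adjusted p = 0.0629). Cellulose synthases (3 of 25 fell), lipid transfer proteins (2 of 26 fell), hypoxia and fermentation genes (4 of 20 fell), disease resistance genes of the NLR class (2 of 22 rose, 1 fell) and transposon-annotated genes (11 of 100 rose, 25 fell) had medians of -0.40, -0.36, -0.34, -0.44 and -0.60, which after scaling turned to 0.56, 0.66, 0.60, 0.17 and 0.0633. Adjusted over the list alone none of the cellulose synthases passed, the other calls being 2 falls, 4 falls, 2 rises and 1 fall, and 11 rises and 32 falls. After scaling they were 0 for cellulose synthases, 1 rise, 2 rises, 4 rises, and 14 rises and 10 falls. With an estimated correlation each of these lists had an adjusted p of 0.838.

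Their leading members included cellulose synthase-like D4 (LOC_Os12g36890), mannan synthase 11 (LOC_Os08g33740) and xyloglucan glycosyltransferase 7 (LOC_Os05g43530), with log2 fold changes of -1.36, -1.12 and -1.16. Lipid transfer proteins LOC_Os10g36170 and LOC_Os11g40530 fell by 2.30 and 1.81 on the log2 scale, and LOC_Os11g24070 had 38.2 ± 31.1 TPM in the wild type and 121 ± 11.9 in the mutant (SD, n = 3; limma adjusted p = 0.0597). The pattern of the hypoxia and fermentation list takes in any gene described as an alcohol dehydrogenase, whether or not it acts in fermentation. In it cinnamyl alcohol dehydrogenase 2 (LOC_Os02g09490), D-lactate dehydrogenase (LOC_Os07g06890) and alcohol dehydrogenase class-3 (LOC_Os02g57040) had log2 fold changes of -1.72, -1.77 and -1.74. None of these calls held after scaling. Resistance gene RGA4 (LOC_Os02g18000) rose from 0.40 ± 0.31 to 2.84 ± 0.29 TPM (SD, n = 3; limma adjusted p = 0.0380, and also past the threshold after scaling), and RGA2 (LOC_Os05g41310) fell by 1.81 on TPM only. The RICESLEEPER 2 gene (LOC_Os03g36550), a domesticated transposase, had 11.32, 7.23 and 10.28 TPM in the wild type and 0, 0.02 and 0.05 in the mutant (limma adjusted p = 0.0010).

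Annotation terms of protein synthesis were enriched among the genes that fell. Of 821 terms with 10 to 500 tested genes, 98 passed among the fallen genes and none among the risen ones by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. The pathway term Ribosome had 240 of 287 genes fallen, and structural constituent of ribosome had 266 of 355. All 17 genes of the translation initiation factor 3 complex fell. Proteasome (37 of 61) and oxidative phosphorylation (58 of 107) were also enriched. At an unadjusted p under 0.05 there were 163 terms among fallen and 11 among risen genes. With resampling matched on mean expression 62 terms passed among fallen genes. Both tests treat genes as independent, while cytosolic ribosomal protein genes had an estimated correlation of 0.95 with each other. With calls made after median-of-ratios scaling no term passed Fisher's exact test among fallen genes (7 at an unadjusted p under 0.05), and 5 passed among risen ones. Those 5 rested on the same 4 genes (LOC_Os01g09030, LOC_Os01g40450, LOC_Os08g37470 and LOC_Os12g42860), named after their values were seen. 3 of them are annotated as 2-aminoethanethiol dioxygenases, a class whose plant members include oxygen sensors.

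Splicing differed in 18 events of 18 genes, and some of these were complete switches between 2 forms. Of 12313 events with reads, 5471 had at least 20 reads in every library and were tested by a quasi-binomial model, with an inclusion level difference of at least 0.1 required. Among the changed events 7 had more and 11 less inclusion in the mutant (exact binomial p = 0.481). They were 8 skipped exons, 2 mutually exclusive exons, 5 alternative 3' splice sites, 2 alternative 5' splice sites and 1 retained intron. At an unadjusted p under 0.05 there were 395 events. The count of 18 was 30 with at least 10 reads, 10 with at least 50 reads, and 9 to 21 with 1 mutant library left out. The deposited tables held 3 wild-type libraries for skipped exons and 2 for the other kinds. Coordinates are as the tables give them, since the genome build is not given in the sources used here.

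In a gene annotated as a tetratricopeptide repeat protein (LOC_Os02g29210, chromosome 2, 17334407 to 17335368) the intron was retained at 1 in both wild-type libraries. It was retained at 0.0078 ± 0.0018 in the mutant (SD, n = 3, limma-moderated adjusted p = 1.22e-04, at least 23 reads per library). In a lysine-specific demethylase 3A gene (LOC_Os03g31594, chromosome 3, 18041182 to 18041873) the alternative 3' splice site was used at 1 in both wild-type libraries and at 0 in all 3 mutant libraries (limma-moderated adjusted p = 4.95e-06, at least 30 reads per library). The gene annotated Dof zinc finger protein DOF1.8 (LOC_Os02g15350, chromosome 2, 8590287 to 8591781) had the smallest p of all events. Inclusion was at 0.34 ± 0.03 in the mutant (SD, n = 3) and 2.23e-04 in the wild type (mean of n = 2, limma-moderated adjusted p = 1.52e-07, at least 1468 reads per library). A skipped exon of an ankyrin repeat kinase gene (LOC_Os02g29140, 17260434 to 17260583) was included at 1 in every mutant library and at 0.64 ± 0.08 in the wild type (SD, n = 3; limma-moderated adjusted p = 3.77e-05). A skipped exon of LOC_Os03g29350, annotated as a calcium channel subunit (chromosome 3, 16697114 to 16697166), was included at 0.34 ± 0.11 in the mutant (SD, n = 3) and at 0 in all 3 wild-type libraries (limma-moderated adjusted p = 6.62e-04).

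Mutually exclusive exons changed in a putative coatomer subunit beta'-3 gene (LOC_Os02g11830, chromosome 2, 6123115 to 6123231), with inclusion of 0.95 ± 0.05 in the mutant (SD, n = 3) and 0.47 ± 0.04 in the wild type (SD, n = 2; limma-moderated adjusted p = 0.0026). Smaller changes were called in ribosomal protein S9-2 (LOC_Os11g38959, chromosome 11, 23181093 to 23181474; difference -0.13, limma-moderated adjusted p = 0.0434), the rcd1 gene (LOC_Os02g19420, chromosome 2, 11340582 to 11340772; -0.15, limma-moderated adjusted p = 0.0193) and a Dr1-associated corepressor (LOC_Os11g34200, chromosome 11, 20025967 to 20026310; -0.16, limma-moderated adjusted p = 0.0280). Each of these 3 lost its call in at least 4 of the 5 fits that left out 1 of its libraries. The authors' deposited table called 574 events at a false discovery rate under 0.05 with a difference of at least 0.1. Of those calls, 160 were of events tested here, and all 18 events changed here were among them with the same sign.

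**Figure D3:**
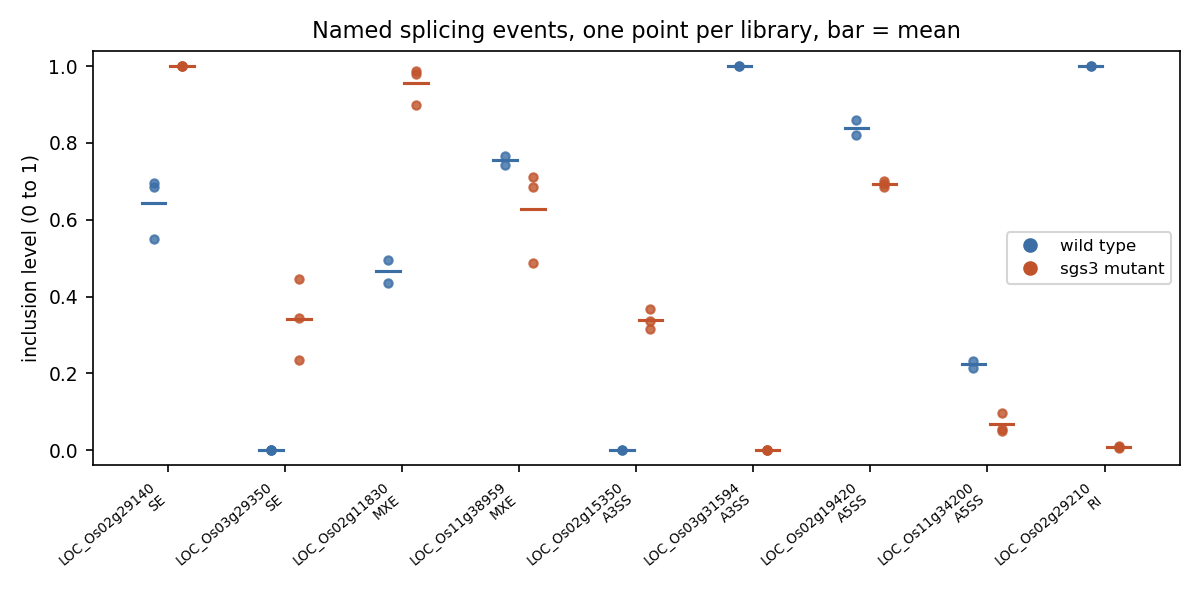
Inclusion level (0 to 1) of the 9 named splicing events in each library, wild type in blue and mutant in orange, with short bars at the group means. LOC_Os03g31594 and LOC_Os02g29210 lie at 1 in the wild type and at 0 or 0.0078 in the mutant.

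Genes with changed splicing were not enriched among genes whose expression changed on TPM, and calls after scaling were too few to tell. Of 2971 genes tested for both, 792 changed in expression and 17 in splicing, and 4 changed in both where 4.53 would be met by chance. The odds ratio was 0.85 (95% interval 0.20 to 2.75, two-sided Fisher's exact p = 1). With the authors' calls from the authors' deposited table the overlap was lower than chance, with 41 genes where 56.5 were expected (odds ratio 0.64, Fisher's exact p = 0.0123). Of the authors' 574 calls only 160 were of events tested here, so this overlap rests on an unlike set of events. Expression level was not adjusted for in it. With gene calls after scaling the direction turned, with 1 gene in both where 0.183 were expected (odds ratio 5.88, 95% interval 0.136 to 40.2, Fisher's exact p = 0.169).

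Genes called on both scales were unevenly spread over the chromosomes, and those seen in 1 genotype only shared this. Chromosome 11 had 47 of its 788 tested genes called (5.96%), against 1.33% on chromosome 1 and 1.36% on chromosome 4 (permutation p = 1e-04 over 12 chromosomes, the smallest that 10000 draws can give). The draws treat genes as independent, while called genes lay near each other, so this p may be too small. There were 19 genes at 5 TPM or more in every mutant library and 0.5 or less in every wild-type library, and 26 of the opposite kind. Chromosomes 11, 10 and 2, with 788, 789 and 1958 tested genes, held 9, 8 and 7 of these 45 genes. They were selected after the data were seen, and 10 of them carried a description. Some of them, such as LOC_Os11g39940, were also called on both scales, so their spread is not separate evidence. A further example beyond those above was peroxisomal hydroxy-acid oxidase GLO1 (LOC_Os08g09860), listed at 0 in the wild type and at 11.25, 13.5 and 22.09 TPM in the mutant.

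**Figure D4:**
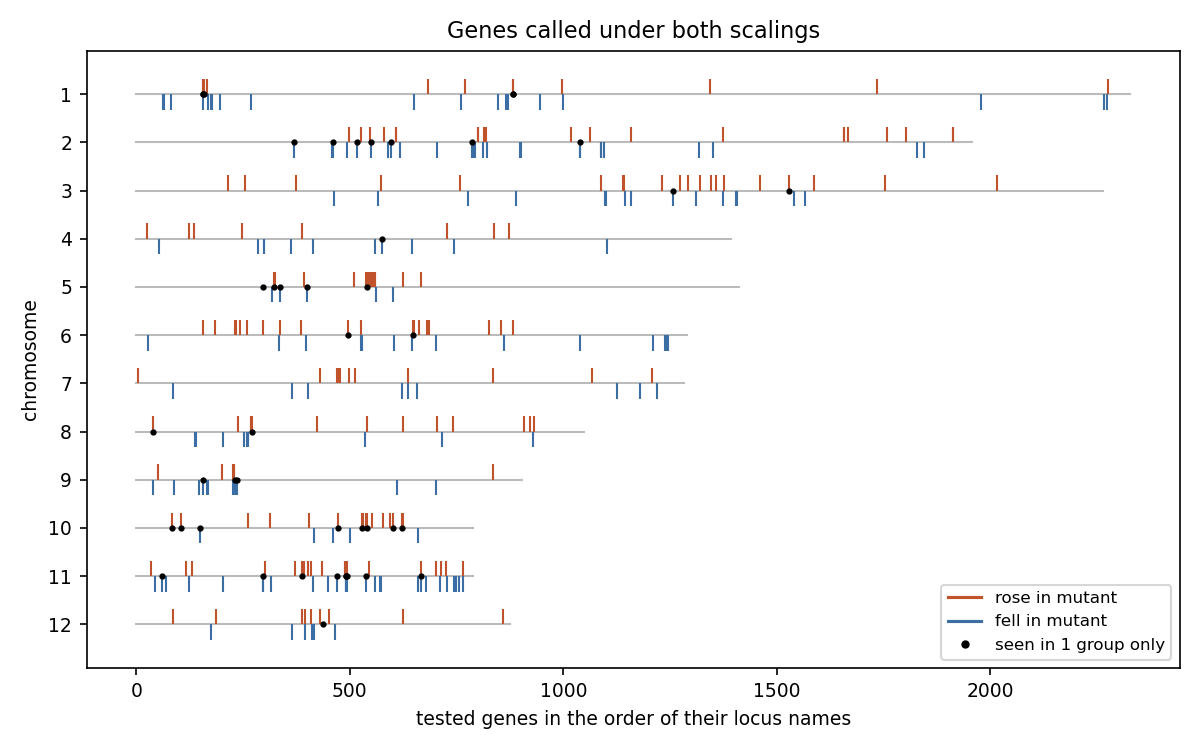
Position, in the order of locus names, of the tested genes called on both scales along the 12 chromosomes, with ticks above the line for 171 rises and below it for 160 falls in the mutant. Black dots mark the 45 genes seen in 1 genotype only; chromosome 11 has the densest ticks, 47 of 788 tested genes.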

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

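The pseudocounts, the scaling combined with leaving out libraries, the quantile normalization, the 5 TPM filter and the calls after scaling for terms and overlap were tried only after the data were seen. The 4548 gene calls stayed within 1.5 times that count with pseudocounts of 0.1 (4134) and 0.5 (4641), a minimum of 5 TPM (4246) and a fold of at least 2 (4465). They dropped to 421 with median-of-ratios scaling, 422 with upper-quartile scaling, 442 with the 20 most abundant genes left out of the total, 476 with quantile normalization and 107 without a filter, which also raised the number of genes tested. An adjusted p under 0.01 gave 102. A fit with the replicate block gave 132, with 2 fewer residual degrees of freedom, though the numbers do not pair the libraries. Leaving out each library in turn gave 94 (without mutant replicate 2) to 8124 (without wild-type replicate 2), and after scaling 151 (without mutant replicate 2) to 2394 (without mutant replicate 3), with 155, 219, 296 and 522 for the others. Why single libraries move the count so far was not tested. Of the 62 named genes, 35 kept their side of the threshold after scaling and 27 called on TPM lost it; with the block 32 kept it and 30 lost it, and no called gene changed direction in any setting. The 14 called lists became 0 with an estimated correlation and 0 by fry; leave-one-out counts were 9 to 21, the lowest with scaling and without mutant replicate 2, where photosynthesis reversed to a median of -0.23. By fry, which tests movement against 0 and not against other genes, 8 lists called up have a direction of down, with medians of -0.31 (starch synthesis), -0.52 (sucrose), -0.0105 (photosynthesis), -0.40 (cellulose synthases), -0.36 (lipid transfer), -0.44 (NLR), -0.34 (hypoxia) and -0.60 (transposon-annotated). Enriched terms went from 98 to 62 with resampling matched on expression and to 5, all among risen genes, with calls after scaling. The 18 splicing events became 30 with at least 10 reads, 10 with at least 50 reads, 29 with no minimum difference and 13 with a difference of at least 0.2. Leave-one-out gave 9 (without the second mutant library listed) to 23 (without the first wild-type library listed, which leaves 1 for the kinds other than exon skipping, assumed to vary like the mutant libraries), and the authors' calls numbered 574. The overlap's odds ratio went from 0.85 to 0.64 with the authors' calls (p = 0.0123, Fisher's exact test), and after scaling it was 5.88, with a p of 0.169 by Fisher's exact test. No paired analysis was possible because the libraries within a splicing cell carry no number. The DESeq2 and limma-voom tests were not run, because they need counts; counts of junction plus exon reads were not used here; and a filter on CPM was not run, because it needs counts too. Gene values carry no depth, so its limit on weakly expressed genes could not be measured.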

Other observations

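The tests of the 3 patterns that follow, and of the other splits, were all chosen only after the results were seen.

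Most gene calls were lower in the mutant, 4295 against 253 rises. With the seed storage list left out of each library's total, 56.7% of 349 calls fell, against 94.4% before, and the median log2 fold change was -0.46, against -0.86 before. Leaving the list out multiplies all other genes of a library by 1 factor, so a smaller downward shift follows from the storage shares by arithmetic. The larger storage share of the mutant libraries is a candidate explanation for part of the one-sidedness, and a downward shift remained. Whether that share comes from the genotype stays open: its exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. Grain-filling stage, which the labels do not give, may also take part and cannot be told apart from genotype here: wild-type replicate 2 minus 1 correlated with the mutant mean minus wild-type replicate 3 at 0.43 across genes after scaling, and the other pairings gave 0.30 and 0.21.

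Genes called under both scalings lay near each other: with the storage list left out, 138 of 322 had a called neighbour within 5 tested genes, not counting pairs with the same description, where 10000 random draws had a median of 58 and at most 92 (permutation p = 1e-04, the smallest they can give). Of the 322 genes 203 have no description, so tandem copies among them were not removed; among the 119 described genes alone, 21 had a described called neighbour of another description, against a median of 8 (permutation p = 0.0019). Segments of different parentage in the mutant and wild-type lines are a candidate explanation, and of 17 genes with changed splicing 6 lay near a called gene (35.3%, against 12.9% of the others; odds ratio 3.69, 95% interval 1.11 to 10.95, Fisher's exact p = 0.0164). Fisher's test counts genes of the same segment as independent, so its p may be too small. Silencing released or set along whole segments would move neighbours together. Of 112 neighbouring pairs 56.25% did, against 49.9% in shuffles (permutation p = 0.101) and a bound set at 75%. The exact binomial interval of 46.6% to 65.6% counts pairs that share a gene as independent, so it is too narrow. The share leans against this explanation, but copies among undescribed pairs, which shared reads would move apart, keep it open. The 12 described pairs are too few to decide (50%, interval 21.1% to 78.9%). Reads shared between near-identical copies also stay open, since 68.0% of 128 described called genes share their description with another gene of the table.

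The read columns of the splicing tables carried group headings that contradict the inclusion columns. In genes changed at least 2-fold in TPM, 97.2% of 4196 events had reads that followed the TPM of the other group, which is consistent with exchanged headings of the read columns. No biological explanation was tested for this pattern.

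The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 4548 changed genes and 421 after scaling, and the highest of the other splits gave 0 for each, so 1 of the 10 splits reached the real value in each case. For gene lists the real split called 14 and the highest other 19, with 3 of the 10 splits reaching the real count. The split with 19 put mutant replicate 3 with wild-type replicates 1 and 2. For exon skipping tested alone the real value was 7 and the highest other 0, and for the other kinds of event, with 10 splits of 5 libraries, they were 13 and 2, with 1 split reaching the real value in each.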
